A study of Mus musculus with 9 samples.

How the data were processed

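RNA was measured in 9 libraries of tumour-associated macrophages, which had been sorted as CD11b+ F4/80+ cells from tumours of the mouse colon carcinoma line MC38. Each of the groups Control, OMVs and IN@OMVs held 3 biological replicates. Whether a replicate is 1 mouse or a pool of mice is not given in the sources used here. The labels give TRIzol extraction and oligo-dT library preparation.

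The deposited table holds expected counts (estimated read counts per gene and library, not normalised). That unit was settled from the values: 88.8% to 89.6% of the values in a library were whole numbers, the rest were fractional, and the columns summed to different totals, from 16813230 to 17288322. The submitters' processing notes name BWA, Bowtie2 and RSEM without versions, and the genome builds mm9 and hg19 without saying which of them made the table. No coordinates are therefore given. The table lists 18042 gene symbols, of which 799 were at 0 in every library, and no mitochondrial genes. A fractional expected count marks reads shared with other sequences, and 2858 genes had one in at least 1 library.

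Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. The quasi-likelihood fit used TMM factors, the filterByExpr filter on the 3 groups and 1 mean per group over all 9 libraries, and each comparison was a contrast of that fit. After the filter 13090 genes were tested. P-values were adjusted by the Benjamini-Hochberg method over these genes within each comparison, with a threshold of 0.05 and no fold threshold. The common dispersion was 0.0172, a biological coefficient of variation of 0.131, with 6 residual degrees of freedom. Fold changes are given on the log2 scale with the standard error of the fit, and levels as CPM (counts scaled to library size) with the SD over 3 libraries.

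Gene lists (27) and cell type marker lists (16, of which 14 had at least 3 measured members) were written before the data were examined, as were the tests and the rule for named genes. Lists were tested with camera of limma 3.58.1 at an inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over lists and comparisons, and tested again with an estimated correlation and with fry. For each list the members past the threshold were counted over all genes tested and again adjusted over the list alone.

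The rule for named genes had 3 parts. In each comparison it took the 10 genes with the largest change in each direction among those past the threshold, with groups that did not overlap and a mean of at least 5 CPM, leaving out predicted and unnamed models. It then took up to 4 members with the smallest p of each list that was called or had at least 3 members past the threshold. A fixed set of 12 macrophage genes was reported whatever their p. Genes outside the rule are marked as chosen after their values were seen.

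The shared response was measured as the correlation and covariance across genes of both fold changes against Control. Because both use the same 3 Control libraries, it was compared with 100 simulated draws of unchanged groups against the same controls.

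The steps were tested on simulated data with changed genes of known fold and the spread of these libraries. In a simulated OMVs against Control comparison, 52.2% of genes changed 1.5-fold, 59.7% of those changed 2-fold and 86.4% of those changed 4-fold were called, with 6 false among 138 calls. For IN@OMVs against Control the shares were 43.3%, 79.1% and 90.9%, with 8 false among 150 calls. For IN@OMVs against OMVs they were 52.2%, 79.1% and 89.4%, with 9 false among 156 calls. A list raised by 0.5 on the log2 scale was called in each comparison with a median between 0.49 and 0.53, and 0 of the other lists were called by camera. Each gene was simulated independently of the others, so this check cannot show false list calls that correlated genes cause.

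The labels do not say what a replicate number marks, so the pairing was checked in the values, as the correlation of deviations from the group means between libraries of the same number. It was 0.53, 0.37 and 0.12 for OMVs and Control and 0.45, 0.31 and 0.15 for IN@OMVs and Control, each over 0.1. Some libraries of different number correlated as well: 0.36 for IN@OMVs 2 with Control 3, 0.29 for IN@OMVs 3 with Control 2. For OMVs 2 with Control 3 it was 0.35. Library 1 correlated negatively with Control or treated libraries of other numbers in these 2 comparisons, so mainly library 1 stood out. The numbers were taken to pair the libraries here by the same-number correlations alone, so the pairing is an assumption. Each comparison was judged by itself only after the calls of both fits had been seen. The fit with the replicate number as a block is printed where it changed a call or moved a count by over 1.5 times, as with 20 genes against 55 for OMVs against Control. For the comparison of IN@OMVs with OMVs the numbers were not taken as pairs. Values with an estimated correlation are without the block except for lists that only the block called, and values by fry or with libraries left out are without it.

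Alternatives covered the replicate number as a block, each library left out in turn, only the 6 libraries of a comparison, DESeq2 size factors and library size alone as scaling, the DESeq2 1.42.0 Wald test, limma-voom, no filter, a stricter filter, other thresholds, and the other list tests. Alternatives for normalised values did not apply to a count table. Leaving out library 1 of every group, and covariates for T cell or fibroblast marker levels, were added after the data had been seen. All 9 libraries of the table were used.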

Results

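Macrophages were sorted as CD11b+ F4/80+ cells from subcutaneous MC38 tumours of female C57BL/6 mice, and their RNA was sequenced in 9 libraries. Control tumours had received solvent, and the others OMVs or IN@OMVs at 12.5 µg of vesicle protein per mouse, injected into the tumour. OMVs is the usual abbreviation of outer membrane vesicles, which bacteria shed. The labels spell out neither that name nor the meaning of IN. Libraries 1, 2 and 3 held 17175517, 17209204 and 16838472 expected counts in IN@OMVs, 17065260, 16971900 and 17288322 in OMVs, and 16813230, 16892205 and 17271784 in Control.

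Other cells' transcripts differed between libraries of 1 group. The mean log2 CPM of 13 T cell markers was 4.22 in IN@OMVs 1, 4.08 in OMVs 1 and 4.23 in Control 1, and lay between 1.95 and 3.10 in the other 6 libraries. Fibroblast markers averaged 4.97 in IN@OMVs 1 and 6.34 to 6.90 in the other 8 libraries. Macrophage markers averaged 9.56 to 10.06 in all 9 libraries and their list was not called in any comparison (camera adjusted p = 0.604 for OMVs against Control, 0.872 for IN@OMVs against Control and 0.716 for IN@OMVs against OMVs).

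**Figure D1:**
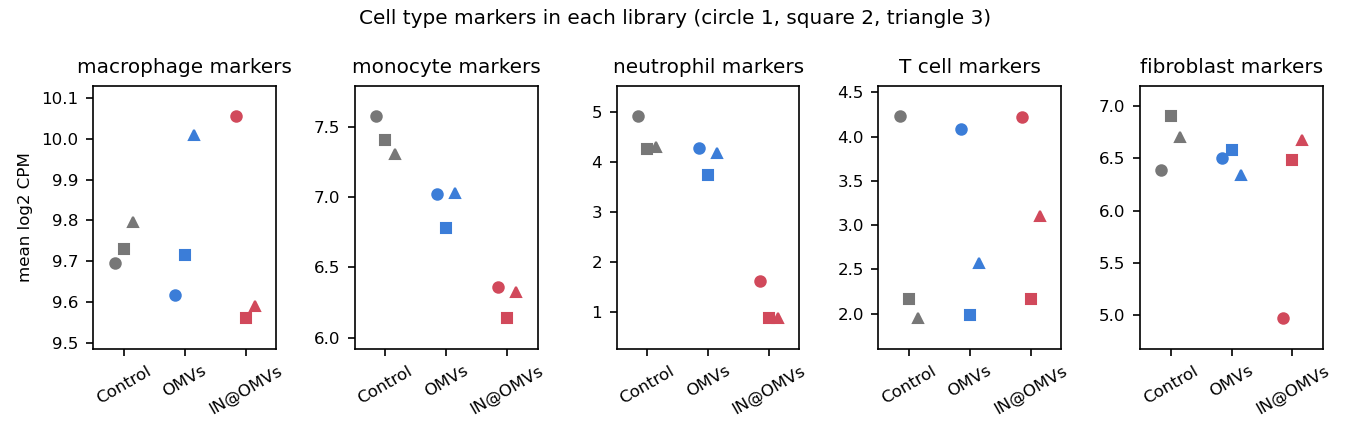
Mean log2 CPM of 5 lists of cell type markers (y axis) in each library, by group (x axis); each point is 1 library and its shape gives the replicate number. Neutrophil markers average 0.87 to 1.61 in IN@OMVs and 3.75 to 4.92 in the other groups, and T cell markers are highest in library 1 of each group.

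The comparison of OMVs with Control asks what the vesicles without IN change in tumour macrophages. Iigp1, an immunity-related GTPase directed at intracellular microbes, rose from 177 ± 3.34 to 307 ± 39.5 CPM (mean ± SD, n = 3 each, log2 fold change 0.79 ± 0.09 SE, adjusted p = 0.0234). The T cell attracting chemokines Cxcl9 (0.86 ± 0.14, adjusted p = 0.0444) and Cxcl10 (0.74 ± 0.12, adjusted p = 0.0459) rose as well. With the replicate number as a block in edgeR the adjusted p was 0.0532 for Iigp1, 0.129 for Cxcl9 and 0.135 for Cxcl10, so none of the 3 passed. Among the genes that fell, the haemoglobin scavenger receptor Cd163 went from 14.8 ± 3.92 to 3.26 ± 1.63 CPM (-2.18 ± 0.33, adjusted p = 0.0363), and the hyaluronan receptor Lyve1 changed by -2.12 ± 0.32 (adjusted p = 0.0382).

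Among 26 measured members of the interferon-gamma response list, 13 rose over all genes tested and 24 rose adjusted over the list alone, with a median of 0.59. With the block 2 members rose over all genes. The list was higher by camera (adjusted p = 1.58e-44) and by fry (adjusted p = 0.0076), but its adjusted p = 0.243 with an estimated correlation. Gbp6 (0.75 ± 0.07), Tgtp2 (0.70 ± 0.07) and Irgm1 (0.55 ± 0.07, adjusted p = 0.0603 with the block) were among the members that rose. Expected counts of Gbp6 and Tgtp2 were fractional in all 9 libraries and those of Iigp1 in 4, so part of their reads was shared with other sequences. T cell markers, whose cells make interferon-gamma, were not called (median -0.03, camera adjusted p = 0.512), and their level varied more between replicates than between groups.

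Of the 22 measured genes of MHC class I antigen presentation, 4 rose adjusted over the list alone (9 with the block) and no member passed over all genes in edgeR, yet all 22 had positive fold changes (camera adjusted p = 5.89e-14, adjusted p = 0.391 with an estimated correlation). Tap2, a peptide transporter, had a log2 fold change of 0.28 ± 0.06. The type I interferon response list (median 0.16, camera adjusted p = 4.72e-06, adjusted p = 0.647 with an estimated correlation) had no member past the threshold over all genes or adjusted over the list alone. NF-kB target genes (median 0.19, camera adjusted p = 1.61e-07, adjusted p = 0.501 with an estimated correlation) had 4 members past the threshold adjusted over the list alone (0 with the block) and none over all genes.

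Classical activation genes were higher as a list (median 0.23, and 0.08 without OMVs 3, camera adjusted p = 7.16e-06, adjusted p = 0.501 with an estimated correlation). The 2 members that rose of 25 were Cxcl9 and Cxcl10 (0 with the block), and 5 rose adjusted over the list alone. Nos2, the inducible nitric oxide synthase, stood at 429 ± 102 CPM in OMVs and 250 ± 17.6 CPM in Control without passing (0.78 ± 0.15, adjusted p = 0.0959). The alternative activation list was not called (camera adjusted p = 0.0812): Retnla (-2.50 ± 0.40), Chil3 (-1.18 ± 0.15) and Cd163 fell, and Pdcd1lg2, which encodes the checkpoint ligand PD-L2, rose (1.04 ± 0.17, adjusted p = 0.04, and 0.127 with the block). Adjusted over the list alone, 2 members rose and 7 fell.

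The chemokine list was called (median 0.22, camera adjusted p = 0.0108, adjusted p = 0.647 with an estimated correlation) with 3 of 25 members higher over all genes, and 1 with the block. Besides Cxcl9 and Cxcl10 this was Cxcl1, which attracts neutrophils (1.29 ± 0.21, adjusted p = 0.04), and adjusted over the list alone 7 members rose and 5 fell. Without OMVs 3 (median 0.09, adjusted p = 0.173) or Control 1 (adjusted p = 0.0866) that list was not called. Genes of MHC class II presentation were called too (median 0.12, camera adjusted p = 0.0108, adjusted p = 0.721 with an estimated correlation), with no member past the threshold over all genes or adjusted over the list alone. This call ended without OMVs 3 (adjusted p = 0.29) or Control 3 (adjusted p = 0.0735), and the median was 0.27 without Control 1. Conventional dendritic cell markers, whose cells carry class II, were not called (median -0.14, camera adjusted p = 0.149).

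The unfolded protein response list was higher (median 0.19, camera adjusted p = 5.69e-09, adjusted p = 0.29 with an estimated correlation), with 1 of 23 members past the threshold over all genes, Herpud1 (0.43 ± 0.06, adjusted p = 0.0267, and 0.0759 with the block), which acts in the degradation of misfolded proteins. Adjusted over the list alone, 9 members rose and 1 fell (4 and 0 with the block). Genes of glycolysis and hypoxia (median 0.14, and 0.08 without OMVs 3, camera adjusted p = 8.51e-08, adjusted p = 0.315 with an estimated correlation) and of cholesterol synthesis (median 0.11, camera adjusted p = 1.63e-06, adjusted p = 0.315 with an estimated correlation) were higher as lists. No member of either passed over all genes, and 4 and 1 passed adjusted over the list alone (2 and 0 with the block).

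NRF2 target genes were lower by camera (median -0.07, adjusted p = 0.0258, adjusted p = 0.538 with an estimated correlation), with Gsr, glutathione reductase, the 1 member that fell (-0.45 ± 0.07), over all genes and adjusted over the list alone. Its adjusted p over all genes was 0.107 with the block. Without OMVs 1 (adjusted p = 0.138) or OMVs 2 (median -0.04, adjusted p = 0.0781) that call ended, and without Control 1 the median was -0.04. The p53 target list (median 0.03, camera adjusted p = 0.0431, adjusted p = 0.592 with an estimated correlation) had no member past the threshold over all genes and 1 adjusted over the list alone. With the block no member passed over the list alone either, and the list was not called (adjusted p = 0.0631). Its median was 0.06 without OMVs 1, 0.10 without OMVs 2 and 0.10 without Control 1. It was not called without OMVs 2 (adjusted p = 0.0551), OMVs 3 (0.124), Control 2 (0.0964) or Control 3 (0.0816). Only the fit with the block called the tumour-associated macrophage list higher (median 0.05, camera adjusted p = 0.0343, and 0.0548 without it) and the immediate early list lower (median -0.12, camera adjusted p = 0.02, and 0.0512 without it). In that fit their adjusted p was 0.791 and 0.477 with an estimated correlation.

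Monocyte markers were lower in OMVs (median -0.40, camera adjusted p = 1.09e-09, adjusted p = 0.148 with an estimated correlation), and 3 of 13 fell: Chil3, the haptoglobin gene Hp (-0.68 ± 0.09, adjusted p = 0.0532 with the block) and the nuclear receptor Nr4a1 (56.9 ± 6.64 against 114 ± 25.2 CPM, adjusted p = 0.0382). Neutrophil markers were lower as a list (median -0.44, and -0.22 without Control 1, camera adjusted p = 0.000192, adjusted p = 0.508 with an estimated correlation), with no member past the threshold over all genes in edgeR and 4 adjusted over the list alone. The block gave 1 and 7 members. Eosinophil (3 genes, median -0.63, camera adjusted p = 0.0169), epithelial or tumour cell (median -0.42, camera adjusted p = 0.0162) and endothelial markers (median 0.19, camera adjusted p = 0.0351) were called as well. With an estimated correlation their adjusted p was 0.409, 0.409 and 0.291. The eosinophil call ended without IN@OMVs 1 (adjusted p = 0.052) or OMVs 2 (0.0841), and the epithelial or tumour cell call without IN@OMVs 1 (0.0573) or Control 1 (median -0.23, adjusted p = 0.0972). Endothelial markers were not called without IN@OMVs 1 (adjusted p = 0.0651), OMVs 1 (median 0.09, adjusted p = 0.102) or Control 1 (median 0.05, adjusted p = 0.171). Their median was 0.32 without Control 2.

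Other genes with large changes included the angiogenic factor Pgf (1.31 ± 0.16, adjusted p = 0.0234), the growth factor gene Nrg1 (0.93 ± 0.11, adjusted p = 0.0234), the leukocyte receptor Slamf8 (0.97 ± 0.11, adjusted p = 0.0234) and the chaperone Hsph1 (0.91 ± 0.14, adjusted p = 0.0375, and 0.0622 with the block). Lower were the organic anion transporter Slco2b1 (-1.67 ± 0.23, adjusted p = 0.0293, and 0.0652 with the block) and the cold-inducible Cirbp (-0.66 ± 0.08, adjusted p = 0.0234, and 0.0603 with the block). In total edgeR called 55 of 13090 genes, 39 higher and 16 lower, and 1105 genes had an unadjusted p under 0.05. Of the 55, 5 were higher and 8 lower by at least 1 log2 unit. With the block 20 genes were called, 12 higher and 8 lower (2 and 5 by at least 1 log2 unit), 15 of them among the 55, and 11 of the 26 named genes passed. The number of calls changed with single libraries: edgeR called 0 genes without OMVs 2, OMVs 3, Control 2 or Control 3 (734, 942, 787 and 803 at an unadjusted p under 0.05), 1 without IN@OMVs 3, 5 without Control 1, 32 without IN@OMVs 2 and 266 without IN@OMVs 1. Over all 9 libraries DESeq2 called 207 genes and limma-voom 36, and none of the 26 named genes that passed kept its call under every omission, while each kept its direction. Over the 9 omissions the log2 change lay between 0.73 and 0.89 for Iigp1, 0.66 and 0.75 for Tgtp2, 0.87 and 0.96 for Hsph1, and -2.67 and -1.97 for Cd163.

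The comparison of IN@OMVs with Control asks what the vesicles with IN change. The guanylate-binding GTPase gene Gbp6 stood at 331 ± 16.8 CPM against 129 ± 10.1 in Control (n = 3 each, log2 fold change 1.36 ± 0.07 SE, adjusted p = 3.19e-05), and the MHC class II gene H2-Aa at 3000 ± 537 against 1660 ± 75.7 CPM (0.86 ± 0.14, adjusted p = 0.00678). Saa3, an acute phase protein gene, fell from 537 ± 83.8 to 6.16 ± 1.57 CPM (-6.44 ± 0.25, adjusted p = 5.88e-06), and the cytokine gene Il1b from 477 ± 100 to 132 ± 22.5 CPM (-1.86 ± 0.17, adjusted p = 0.000488).

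All but 1 of the 26 measured interferon-gamma response genes rose over all genes tested (25), and 26 rose adjusted over the list alone, with a median of 1.15 (camera adjusted p = 2.78e-42, fry adjusted p = 0.000404). With an estimated correlation the adjusted p was 0.243. Tgtp2 (1.56 ± 0.08), Iigp1 (1.67 ± 0.09) and Irgm1 (1.19 ± 0.07) were among them, and Cxcl9 (1.22 ± 0.14) and Cxcl10 (0.99 ± 0.12) rose as well. Gbp2b, another guanylate-binding GTPase, had the largest rise of the named genes (2.77 ± 0.20, adjusted p = 0.00012). T cell markers were not called (median 0.23, camera adjusted p = 0.22) but were with the block (median 0.40, adjusted p = 0.00538, and 0.653 with an estimated correlation), and the T cell marker gene Il7r rose (0.54 ± 0.09), chosen after its value was seen. The mean log2 CPM of the T cell markers was 4.221, 2.165 and 3.103 in IN@OMVs 1, 2 and 3. In Control 1, 2 and 3 it was 4.229, 2.16 and 1.948, so the paired difference in that mean lay in library 3.

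Type I interferon response genes rose in 17 of 26 measured members over all genes and in 25 adjusted over the list alone (median 0.61, camera adjusted p = 5.51e-23, adjusted p = 0.315 with an estimated correlation). Isg15, a ubiquitin-like modifier, changed by 0.81 ± 0.08, and Ifit3, an antiviral RNA-binding protein gene with fractional counts in all 9 libraries, by 1.03 ± 0.10. MHC class I presentation genes rose in 14 of 22 members over all genes and 19 adjusted over the list alone (median 0.52, camera adjusted p = 9.44e-18, adjusted p = 0.315 with an estimated correlation), among them the transactivator Nlrc5 (0.86 ± 0.09) and Tap2 (0.63 ± 0.06). MHC class II presentation genes rose in 7 of 16 members over all genes and 8 adjusted over the list alone (median 0.37, and 0.24 without IN@OMVs 1, camera adjusted p = 1.69e-06, adjusted p = 0.501 with an estimated correlation), including the class II transactivator Ciita (0.89 ± 0.12) and H2-Eb1 (0.90 ± 0.14). Conventional dendritic cell markers were not called (median 0.09, camera adjusted p = 0.282), but 2 of 12 rose over all genes, Clec9a (1.31 ± 0.22) and Batf3 (1.33 ± 0.26), chosen after their values were seen. Which cells the class II transcripts came from was not tested.

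Classical activation genes went both ways and the list was not called (median -0.28, camera adjusted p = 0.0548). Over all genes 3 members rose and 7 fell, and adjusted over the list alone 5 rose and 11 fell. The cytokines Il1a (-1.46 ± 0.15) and Il6 (-3.53 ± 0.34) and the NAD-consuming enzyme gene Cd38 (-2.18 ± 0.17) fell, while Cxcl9 and Cxcl10 rose. Alternative activation genes were higher by camera (median 0.21, adjusted p = 0.0421, adjusted p = 0.656 with an estimated correlation), with 5 of 25 members higher and 3 lower over all genes and 7 and 4 adjusted over the list alone. The lectin gene Mgl2 (1.63 ± 0.13, fractional counts in all 9 libraries) and Pdcd1lg2 (2.00 ± 0.16) rose, and Cd163 (-2.46 ± 0.33) and Chil3 (-1.40 ± 0.15) fell. Without IN@OMVs 1 the alternative activation list was not called (adjusted p = 0.304). Its median was 0.13 without Control 1.

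The tumour-associated macrophage list was higher (median 0.19, camera adjusted p = 0.00585, adjusted p = 0.656 with an estimated correlation) and was not called without IN@OMVs 1 (median 0.07, adjusted p = 0.0969). Of 26 members 6 rose and 1 fell over all genes, and 6 and 2 adjusted over the list alone. The elastase gene Mmp12 rose from 211 ± 17.6 to 717 ± 46.8 CPM (1.76 ± 0.16) and the lysosomal glycoprotein gene Gpnmb by 1.10 ± 0.13, and the gelatinase gene Mmp9 changed by -1.36 ± 0.18. Matrix and angiogenesis factors were lower by camera (median -0.31, adjusted p = 0.0258, adjusted p = 0.486 with an estimated correlation), and not called without IN@OMVs 1 (adjusted p = 0.0955). Over all genes 4 of 26 rose, such as Mmp12 and the collagenase gene Mmp13 (1.90 ± 0.20), and 6 fell, such as Mmp8, a neutrophil collagenase (-2.43 ± 0.15), and Thbs1, thrombospondin 1 (-1.09 ± 0.12). Adjusted over the list alone 5 rose and 8 fell.

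NF-kB target genes were lower (median -0.21, camera adjusted p = 0.000139, adjusted p = 0.647 with an estimated correlation), with 1 of 25 members higher (0 with the block) and 6 lower over all genes and 2 and 10 adjusted over the list alone. Clec4e, a receptor for microbial glycolipids (-1.01 ± 0.12), and Irak3, an inhibitor of Toll-like receptor signalling (-0.90 ± 0.13), fell. Immediate early genes were lower (median -0.47, camera adjusted p = 1.89e-05, adjusted p = 0.321 with an estimated correlation): 9 of 18 fell and 1 rose over all genes, and 10 and 4 did adjusted over the list alone, with Nr4a1 at -2.38 ± 0.17 and Fosb at -1.73 ± 0.16. The cytokine feedback list was lower (median -0.26, camera adjusted p = 0.00824, adjusted p = 0.656 with an estimated correlation), with 6 of 20 members lower and 1 higher both over all genes and adjusted over the list alone. The member that rose was Socs1, an inhibitor of interferon signalling (1.56 ± 0.11), and Socs3 fell (-0.93 ± 0.10). Without IN@OMVs 2 the feedback list was not called (median -0.09, adjusted p = 0.059). It had a median of -0.10 without Control 1.

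Among metabolic lists, cholesterol synthesis was higher (median 0.23, camera adjusted p = 1.08e-08, adjusted p = 0.315 with an estimated correlation), with 8 of 23 members higher over all genes (5 with the block) and 12 adjusted over the list alone, such as Fdps, a farnesyl diphosphate synthase (0.48 ± 0.08). The unfolded protein response list was higher (median 0.17, camera adjusted p = 2.43e-05, adjusted p = 0.315 with an estimated correlation), with 7 of 23 members higher over all genes and 10 adjusted over the list alone, among them Herpud1 (0.60 ± 0.06) and the stress-induced transcription factor gene Ddit3 (0.81 ± 0.10). NRF2 targets were higher by camera (median 0.09, adjusted p = 0.0272, adjusted p = 0.538 with an estimated correlation), with 6 of 23 higher (3 with the block) and 1 lower over all genes and 8 and 1 adjusted over the list alone (8 and 2 with the block). The haem oxygenase gene Hmox1 rose from 401 ± 80.4 to 855 ± 63.9 CPM (1.09 ± 0.18), and Gsr fell (-1.25 ± 0.07). Without IN@OMVs 1 the NRF2 list was not called (median 0.01, adjusted p = 0.259). Its median was 0.16 without IN@OMVs 3.

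Glycolysis and hypoxia genes were called higher (median 0.12, camera adjusted p = 0.0248, adjusted p = 0.656 with an estimated correlation), with 4 of 26 higher and 3 lower over all genes (3 and 1 with the block) and 7 and 3 adjusted over the list alone. The call ended without IN@OMVs 1 (median 0.08, adjusted p = 0.0596), IN@OMVs 2 (adjusted p = 0.0619) or Control 2 (adjusted p = 0.0714). Cell cycle genes were lower (median -0.21, camera adjusted p = 8.89e-05, adjusted p = 0.698 with an estimated correlation), with 2 of 32 lower over all genes and adjusted over the list alone (1 and 11 with the block). These were the centromere histone gene Cenpa (-0.27 ± 0.05) and the cyclin gene Ccnb2 (-0.27 ± 0.07, adjusted p = 0.0748 with the block), and the cell cycle list was not called without IN@OMVs 1 (median -0.12, adjusted p = 0.0576). Cenpa lost its call without IN@OMVs 3, Control 2 or Control 3, and Ccnb2 without any 1 of IN@OMVs 2, IN@OMVs 3, OMVs 2 and the 3 Control libraries. The scavenger receptor Cd36, which takes up lipids, rose by 1.23 ± 0.18 in lists of lipid and phagocytosis genes that were not called.

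Neutrophil markers fell in 11 of 12 measured genes over all genes and in 12 adjusted over the list alone (median -3.44, camera adjusted p = 8.06e-21, adjusted p = 0.148 with an estimated correlation). The calprotectin genes S100a8 and S100a9 went from 216 ± 39.5 to 16.1 ± 3.53 CPM (-3.75 ± 0.20) and from 334 ± 98.1 to 23.9 ± 8.94 CPM (-3.80 ± 0.30). Ngp, a granule protein gene, held 8 reads over the 3 IN@OMVs libraries and 1073 over the 3 Control libraries. Monocyte markers fell in 8 of 13 genes over all genes and 10 adjusted over the list alone (median -0.95, camera adjusted p = 2.57e-09, adjusted p = 0.148 with an estimated correlation). Epithelial or tumour cell markers fell in 3 of 5 measured genes, over all genes and adjusted over the list alone (median -0.56, camera adjusted p = 0.00723, adjusted p = 0.409 with an estimated correlation). Eosinophil and fibroblast markers were lower (adjusted p = 0.041 and 0.0187) and NK cell and erythroid or platelet markers higher (adjusted p = 0.0167 and 0.011) by camera only with the block. In that fit their adjusted p was 0.608, 0.659, 0.657 and 0.461 with an estimated correlation. Without the block these 4 lists were not called (adjusted p = 0.0727, 0.0727, 0.278 and 0.0571). Fibroblast markers averaged 4.97 log2 CPM in IN@OMVs 1, while 6.48 in IN@OMVs 2 and 6.67 in IN@OMVs 3 lay within the Control range of 6.39 to 6.90.

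Moving with these markers, the acute phase and iron genes Hp (-4.20 ± 0.11, adjusted p = 3.49e-07) and Lcn2 (-4.04 ± 0.17, adjusted p = 1.03e-05) and the acute phase glycoprotein gene Lrg1 (-4.34 ± 0.32, adjusted p = 0.00012) fell. Chemokines that attract neutrophils, Cxcl2 (-1.31 ± 0.12) and Cxcl3 (71.0 ± 4.42 against 142 ± 10.2 CPM), fell too, and the chemokine list was not called (camera adjusted p = 0.924). Of its 25 members 5 rose and 6 fell over all genes and 10 and 9 adjusted over the list alone, with a median of 0.23 and a mean of -0.24. The iron list was not called by camera (median -0.01, mean -0.47, adjusted p = 0.183) but was lower by fry (adjusted p = 0.0121), with 3 of 19 higher and 5 lower over all genes and 4 and 5 adjusted over the list alone. Of genes for sensing bacteria, the endotoxin co-receptor Cd14 fell (-1.07 ± 0.12) and Cd180, a regulator of endotoxin responses, rose (0.85 ± 0.13), and that list was not called (median 0.07, mean -0.06, camera adjusted p = 0.426).

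Further named genes that rose were Dnase1l3, an extracellular nuclease (2.02 ± 0.21), Ch25h, cholesterol 25-hydroxylase (1.70 ± 0.18), the integrin gene Itga8 (2.09 ± 0.18), Sectm1a (1.83 ± 0.16) and Tlr12 (1.72 ± 0.20). In total edgeR called 858 of 13090 genes, 434 higher and 424 lower, and 217 changed by at least 1 log2 unit, 77 higher and 140 lower. The count was 1635 without IN@OMVs 1, 496 without IN@OMVs 3, 486 without Control 1, 400 without Control 2 and 393 without Control 3. Of the 98 named genes that passed, 76 kept their call under each of the 9 omissions.

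**Figure D2:**
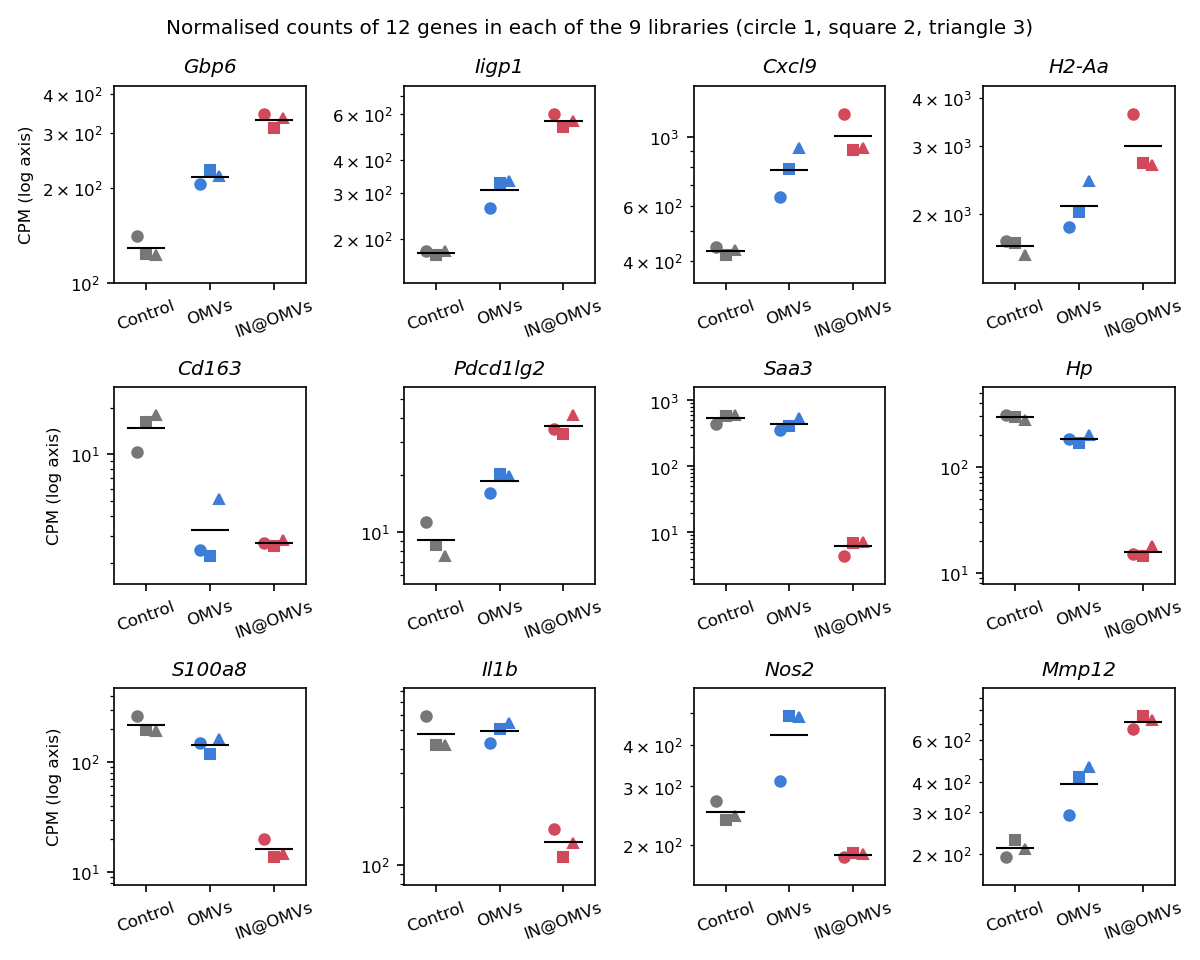
CPM on a log axis (y axis) of 12 named genes in each library, by group (x axis); points are libraries, shapes give the replicate number and bars the group mean. Saa3 lies at 6.16 CPM on average in IN@OMVs and 537 in Control, while Gbp6 is lowest in Control (129), higher in OMVs (218) and highest in IN@OMVs (331).

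The comparison of IN@OMVs with OMVs asks what IN adds at the same vesicle dose. Iigp1 stood at 563 ± 31.7 against 307 ± 39.5 CPM (n = 3 each, log2 fold change 0.88 ± 0.09 SE, adjusted p = 0.00162) and Gbp2b at 14.6 ± 2.34 against 2.28 ± 0.25 CPM (2.67 ± 0.20, adjusted p = 0.000371). Il1b was lower at 132 ± 22.5 against 495 ± 58.8 CPM (-1.91 ± 0.17, adjusted p = 0.000838), as was Nos2 at 186 ± 2.70 against 429 ± 102 CPM (-1.20 ± 0.15, adjusted p = 0.00436). Retnla, a marker of alternative activation, was higher at 4.34 ± 0.92 against 0.60 ± 0.05 CPM (2.83 ± 0.40, adjusted p = 0.00634). Its level in Control 1, 2 and 3 was 1.67, 4.15 and 4.55 CPM, which overlaps that in IN@OMVs, so OMVs was the low group. Neutrophil markers were lower as a list (median -3.11, camera adjusted p = 3.64e-24, adjusted p = 0.148 with an estimated correlation).

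Interferon-gamma response genes rose in 18 of 26 members over all genes and 24 adjusted over the list alone (median 0.58, camera adjusted p = 4.75e-29, fry adjusted p = 0.0076, adjusted p = 0.29 with an estimated correlation). Cxcl9 (0.36 ± 0.14, adjusted p = 0.282) and Cxcl10 (0.25 ± 0.12, adjusted p = 0.408) did not pass. Type I interferon genes rose in 11 of 26 members over all genes and 21 adjusted over the list alone (median 0.44, camera adjusted p = 1.32e-21, adjusted p = 0.315 with an estimated correlation), with Isg15 at 0.60 ± 0.08. MHC class I genes rose in 3 of 22 over all genes and 12 adjusted over the list alone (median 0.31, and 0.18 without IN@OMVs 1, camera adjusted p = 2.01e-09, adjusted p = 0.501 with an estimated correlation). These 3 were Tap2, Nlrc5 and Psmb10, and each lost its call without IN@OMVs 3, OMVs 1, OMVs 2 or OMVs 3, and Tap2 and Psmb10 without Control 2 or Control 3 as well. The MHC class II list was higher (median 0.39, and 0.19 without IN@OMVs 1, camera adjusted p = 1.14e-05, adjusted p = 0.538 with an estimated correlation) with no member past the threshold over all genes in edgeR and 6 adjusted over the list alone. Conventional dendritic cell markers were higher as well (median 0.34, camera adjusted p = 0.00937, adjusted p = 0.505 with an estimated correlation), with 2 of 12 higher over all genes and 4 adjusted over the list alone, and were not called without IN@OMVs 1 (median 0.20, adjusted p = 0.052). Their median was 0.55 without OMVs 1. Whether class II rose in macrophages or through more dendritic cells was not tested. T cell markers were not called (median 0.20, camera adjusted p = 0.324).

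Classical activation genes fell in 10 of 25 members over all genes, and adjusted over the list alone 12 fell and 2 rose (median -0.71, camera adjusted p = 9.64e-06, adjusted p = 0.501 with an estimated correlation). Without OMVs 3 the median was -0.15 and the list was still called (adjusted p = 0.000672). Besides Il1b and Nos2 these included Ptgs2, which encodes cyclooxygenase 2 (-1.30 ± 0.11), the formyl peptide receptor gene Fpr2 (-1.18 ± 0.12) and Cd38 (-2.39 ± 0.17). Neutrophil markers were lower in the same libraries, and which cells these transcripts came from was not tested. NF-kB targets fell in 11 of 25 members over all genes, and adjusted over the list alone 18 fell and 1 rose (median -0.36, camera adjusted p = 1.53e-14, adjusted p = 0.315 with an estimated correlation), with the inhibitor gene Nfkbia at -0.64 ± 0.08. Alternative activation genes rose in 7 of 25 members over all genes, and adjusted over the list alone 10 rose and 1 fell (median 0.13, 0.27 without IN@OMVs 1 or OMVs 3, camera adjusted p = 3.65e-05, adjusted p = 0.391 with an estimated correlation). The eosinophil-attracting chemokine gene Ccl24 (1.42 ± 0.22), Mgl2 (1.05 ± 0.13) and Pdcd1lg2 (0.96 ± 0.16) were among them, and Pdcd1lg2 lost its call without IN@OMVs 3 or OMVs 1.

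Immediate early genes fell in 5 of 18 members over all genes, and adjusted over the list alone 11 fell and 2 rose (median -0.40, camera adjusted p = 2.35e-07, adjusted p = 0.315 with an estimated correlation), with Nr4a1 at -1.38 ± 0.16. The cytokine feedback list was lower (median -0.33, -0.15 without IN@OMVs 2 and -0.20 without IN@OMVs 3, camera adjusted p = 0.0028, adjusted p = 0.647 with an estimated correlation), with 6 of 20 lower and Socs1 (0.80 ± 0.10) higher over all genes, and 8 and 1 adjusted over the list alone. Matrix and angiogenesis factors were lower (median -0.16, camera adjusted p = 0.0028, adjusted p = 0.315 with an estimated correlation), with 6 of 26 lower and 2 higher over all genes and 8 and 3 adjusted over the list alone. Pgf (-1.62 ± 0.16) fell and the urokinase gene Plau (1.05 ± 0.14) rose, and the matrix list was not called without IN@OMVs 1 (adjusted p = 0.0576). Pgf stood at 6.87 to 7.41 CPM in IN@OMVs, 8.18 to 9.76 in Control and 17.4 to 27.4 in OMVs, so mainly OMVs was the high group. NRF2 targets were higher (median 0.13, 0.03 without IN@OMVs 1 and 0.19 without OMVs 3, camera adjusted p = 0.000161, adjusted p = 0.315 with an estimated correlation), with 4 of 23 higher and 1 lower over all genes and 8 and 1 adjusted over the list alone, Hmox1 rising by 1.27 ± 0.18.

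Iron handling genes were lower by camera (median -0.07, mean -0.43, adjusted p = 0.0149, adjusted p = 0.647 with an estimated correlation), with 5 of 19 lower and 2 higher over all genes and 6 and 3 adjusted over the list alone. The largest falls were those of Lcn2 (-3.65 ± 0.17) and Hp (-3.52 ± 0.11), beside a median of -3.11 for neutrophil markers (adjusted p = 0.148 with an estimated correlation). The iron exporter gene Slc40a1 rose (1.34 ± 0.18) and the transferrin receptor gene Tfrc fell (-0.73 ± 0.08). Without IN@OMVs 2 (median -0.02, adjusted p = 0.0833) or OMVs 3 (median -0.02, adjusted p = 0.165) the iron list was not called. Its median was -0.20 without IN@OMVs 1 and -0.13 without OMVs 1. Cholesterol synthesis genes were higher as a list (median 0.10, camera adjusted p = 0.000406, adjusted p = 0.477 with an estimated correlation), and cell cycle genes lower (median -0.23, and -0.15 without IN@OMVs 1, camera adjusted p = 1.55e-08, adjusted p = 0.584 with an estimated correlation). Neither had a member past the threshold over all genes or adjusted over the list alone, and the cholesterol call ended without OMVs 1 (adjusted p = 0.0533). The lipid receptor gene Cd36 rose (1.54 ± 0.19), and the chemokine list was not called (median -0.03, mean -0.29, camera adjusted p = 0.327).

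Neutrophil markers fell in 11 of 12 measured genes over all genes and in 12 adjusted over the list alone (adjusted p = 0.148 with an estimated correlation). With them Saa3 (-6.13 ± 0.24), Lcn2 (-3.65 ± 0.17), Csf3, which encodes the neutrophil growth factor G-CSF (-3.88 ± 0.25), and Cxcl1 (-2.82 ± 0.22) fell. Monocyte markers fell in 4 of 13 genes over all genes and 6 adjusted over the list alone (median -0.32, camera adjusted p = 7.61e-05, adjusted p = 0.374 with an estimated correlation).

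In total edgeR called 373 of 13090 genes, 144 higher and 229 lower, of which 110 changed by at least 1 log2 unit, 21 higher and 89 lower. The count was 786 without IN@OMVs 1, 191 without IN@OMVs 3, 212 without OMVs 1, 180 without OMVs 2, 199 without OMVs 3 and 243 without Control 3. Of the 71 named genes that passed, 57 kept their call under each of the 9 omissions.

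**Figure D3:**
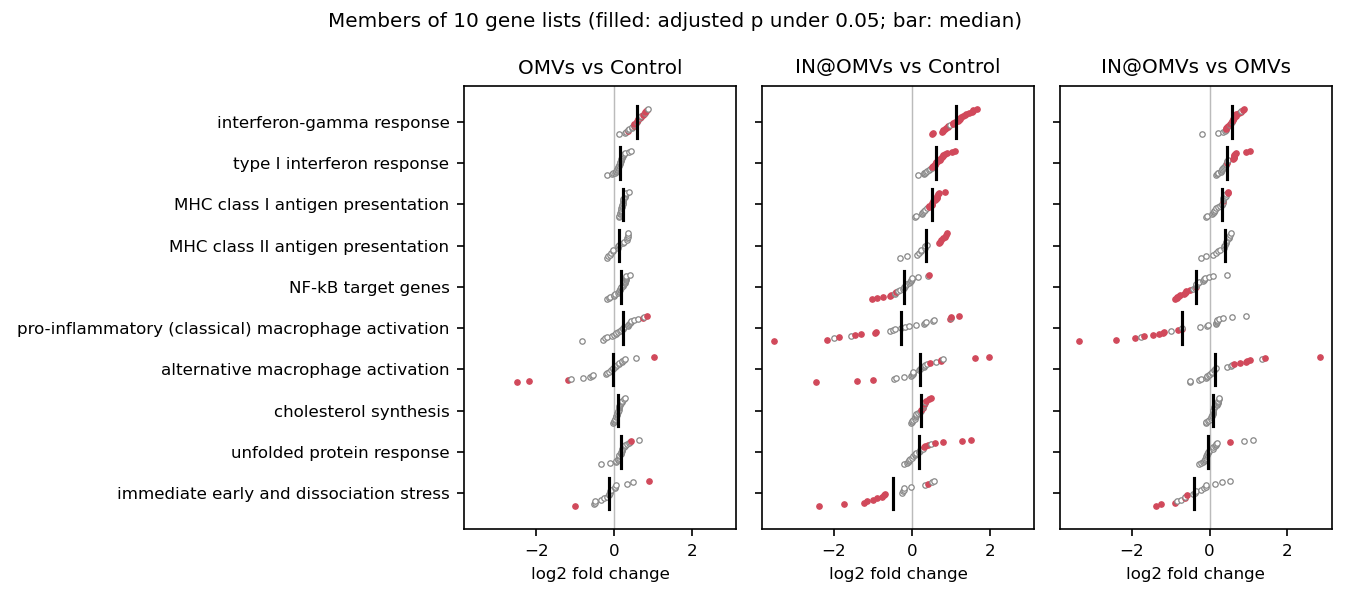
Log2 fold changes (x axis) of the measured members of 10 gene lists (y axis) in the 3 comparisons; filled points passed an adjusted p of 0.05 over all genes and black bars are list medians. The interferon-gamma response list has medians of 0.59, 1.15 and 0.58, and 25 of its 26 members lie to the right of 0 for IN@OMVs against OMVs.

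Of the fixed set of 12 macrophage genes, Nos2, Il1b, Cxcl9, Cxcl10 and Cd274 passed in at least 1 comparison. The sort markers Adgre1, which encodes F4/80 (-0.11 ± 0.17 for IN@OMVs against Control, adjusted p = 0.795), and Itgam, which encodes CD11b (-0.50 ± 0.13, adjusted p = 0.0512), did not pass in any comparison. Neither did Arg1, Mrc1, Spp1, Tnf or Il10, with log2 fold changes of 0.21 ± 0.13, 0.20 ± 0.16, -0.09 ± 0.08, 0.36 ± 0.16 and -0.46 ± 0.38 for IN@OMVs against Control. Cd274, which encodes the checkpoint ligand PD-L1, stood at 143 ± 9.32 CPM in Control, 233 ± 31.9 in OMVs and 205 ± 28.1 in IN@OMVs. It passed for IN@OMVs against Control (0.52 ± 0.12, adjusted p = 0.0412, and 0.0805 with the block) but not for OMVs against Control (0.70 ± 0.12, adjusted p = 0.0615), and the difference between both treatments was -0.18 ± 0.12 (adjusted p = 0.579). The Cd274 call ended without IN@OMVs 3, OMVs 2 or any 1 of the 3 Control libraries.

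Both treatments were also compared for a shared response. Of the genes called against Control, 32 were higher and 9 lower in both, and 1 was called in opposite directions. In 100 simulated draws of unchanged groups with the same controls, 0 to 1 genes were higher and 0 lower in both. Groups without any change give few calls, so these simulated counts had to lie near 0 and do not test sharing. Independent lists of these sizes, which leave out the shared controls, would share 1.29 and 0.52. The 3 controls cannot be split into parts of at least 2 libraries each, so part of the excess in these counts may come from the shared Control libraries. With the block 8 genes were higher in both and 7 lower. Across 13090 genes, which are not independent replicates, the covariance of the fold changes was 0.0509, against 0.0249 to 0.0307 in these draws. Pearson's r of 0.525 lay inside the simulated range of 0.458 to 0.531, and Spearman's rho of 0.5001 above 0.436 to 0.472. Genes and libraries were drawn independently, so the draws held neither shifts shared by many genes nor paired libraries. Such shifts could widen the simulated ranges, and no paired draws were run. Without Control 1 Pearson's r was 0.621 and without OMVs 1 it was 0.435.

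Without the block, camera called these lists in no comparison: endotoxin and bacterial sensing, inflammasome and pyroptosis, immune checkpoint ligands and receptors. Nor did it call tryptophan and AhR genes, phagocytosis receptors, lysosome, oxidative phosphorylation, or lipid efflux and LXR or PPAR targets. Marker lists of macrophages, plasmacytoid dendritic cells, T cells, NK cells, B cells and fibroblasts were not called in that fit either. The same held for erythroid cells and platelets, and for muscle and skin. With the block, camera called oxidative phosphorylation for IN@OMVs against OMVs. T cell, NK cell, fibroblast and erythroid or platelet markers were then called for IN@OMVs against Control and against OMVs.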

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

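Omitting library 1 of every group and the T cell and fibroblast covariates were chosen after the data had been seen; the other alternatives were planned. No named gene, gene list or marker list that was called changed direction under any alternative run. For gene lists called in the main fit 717 results kept their side of the threshold and 103 lost the call, and for marker lists so called 186 and 34. Lists not called in the main fit were outside this tally, so it could not count a list that gained a call. Of the results for named genes 4997 kept their side, 392 lost the call and 171 gained one. For OMVs against Control the main count of 55 was 115 with only the 6 libraries of the comparison, 207 with DESeq2, 36 with limma-voom, 94 at an adjusted p under 0.1, 13 with a log2 change of at least 1, 313 without library 1 of every group, 386 with the fibroblast covariate, and 0 to 266 with 1 library left out. For IN@OMVs against Control 858 became 519 with only its 6 libraries, 217 with a log2 change of at least 1, 1475 without library 1 of every group, 1972 with the fibroblast covariate, and 393 to 1635 with 1 library left out. For IN@OMVs against OMVs 373 became 195 with only its 6 libraries, 646 with DESeq2, 601 at an adjusted p under 0.1, 110 with a log2 change of at least 1, 844 without library 1 of every group, 963 with the fibroblast covariate, and 180 to 786 with 1 library left out. Fewer or more genes past another threshold follow from how those alternatives are built. For all others, those with fewer libraries included, the cause was not tested. IN@OMVs libraries do not enter the means of OMVs or Control. The 266 calls for OMVs against Control without IN@OMVs 1 can therefore come only through the shared filter, scaling or spread estimate. Which of these acted was not tested. Between IN@OMVs replicates the chi-square of the counts per degree of freedom was 42 and 34.7 with library 1, and 3.69 without it.

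The correlation of both responses (0.525) was 0.654 over genes past the threshold in either comparison and 0.435 to 0.621 with 1 library left out. Of 81 gene list tests 41 were called by camera, 19 by fry and 0 by camera with an estimated correlation. Of 42 marker tests 11 were called by camera, 7 with the fibroblast covariate, 0 with an estimated correlation, 11 by fry, and 7 to 18 with 1 library left out. Here the cause was not tested either.

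Between IN@OMVs and OMVs, correlations of libraries with the same number ran from -0.37 to 0.51, so the numbers were not taken as pairs there. Library 1 of both groups was nevertheless high in T cell markers (mean log2 CPM 4.22 and 4.08). Of all 9 libraries, 4 correlated best with their own number in both other groups. With the replicate number as a block 306 genes were called for IN@OMVs against OMVs. Cell cycle genes then fell in 13 members adjusted over the list alone. Over all comparisons that fit called 44 gene list tests and 20 marker tests. For OMVs against Control the paired fit called 20 genes (15 shared with the 55), and for IN@OMVs against Control 673 (623 shared with the 858). In these 2 comparisons it changed 15 of the 26 and 6 of the 98 calls of named genes, 3 calls of gene lists and 5 of marker lists. Among the lost calls were Gbp4 (adjusted p = 0.0652), Htra3 (0.0785), Hopx (0.117) and Slc4a11 (0.0735) for OMVs, and Axl (0.0549), Fcgr4 (0.0699), Hif1a (0.0613) and Il4i1 (0.0528) for IN@OMVs. In these 2 comparisons it changed no other call of a named gene or list. For IN@OMVs against OMVs the block ended the call of Axl (adjusted p = 0.0694) and added Tapbpl (0.0257). By camera it added the tumour-associated macrophage (0.0471) and oxidative phosphorylation (0.04) lists there. It also added T cell (0.0148), NK cell (0.0393), fibroblast (0.0437) and erythroid or platelet markers (0.0341). With an estimated correlation these added lists had adjusted p of 0.608 to 0.845 in that fit. Depth differed little between libraries, with totals between 16813230 and 17288322, and whether it limited the calls was not tested.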

Other observations

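All gene groups and tests in this part were chosen after the values had been seen, except the counts over other splits of the libraries. Heat shock chaperones were higher in OMVs than in Control (median 0.27, camera adjusted p = 1.9e-15, adjusted p = 0.0095 with an estimated correlation). Of 18 genes 17 had positive fold changes, and Hsph1 (0.91), Chordc1 (0.44) and Bag3 (0.33) passed over all genes, but only Chordc1 with the replicate number as a block (adjusted p = 0.0622 for Hsph1 and 0.0997 for Bag3). Cold-inducible RNA-binding protein genes were lower (adjusted p = 0.0095 with an estimated correlation), with Cirbp (-0.66) and Rbm3 (-0.41) past the threshold of 3 measured, and 0 with the block (adjusted p = 0.0603 for both). None of these calls is independent evidence, because the groups were drawn up from the same libraries, and in that comparison edgeR called 0 genes without OMVs 2 (734 at an unadjusted p under 0.05).

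In IN@OMVs against Control, clock output genes were higher by camera (adjusted p = 0.00257, adjusted p = 0.304 with an estimated correlation): Dbp (1.22), Nr1d1 (1.18), Bhlhe41 (0.96), Ciart (0.91) and Nr1d2 (0.47, adjusted p = 0.0546 with the block) rose, and Cry1 (-0.38) fell, of 13 measured. Nfil3, a repressor whose rhythm runs opposite to that of Dbp, fell (-0.79). Targets of the integrated stress response were higher (camera adjusted p = 0.00108, adjusted p = 0.34 with an estimated correlation), with 6 of 16 past the threshold, among them Gdf15 (1.56), Chac1 (1.53, adjusted p = 0.0595 with the block) and Trib3 (1.28). The mean log2 CPM of these targets was 4.291, 5.005 and 4.902 in IN@OMVs 1, 2 and 3, and 4.306 to 4.322 in Control. IN@OMVs 1 thus lay under all Control libraries in that mean. Stromal matrix genes had no member past the threshold over all genes in edgeR or adjusted over the list alone (median -0.36, camera adjusted p = 0.0113, adjusted p = 0.649 with an estimated correlation). Their mean log2 CPM was 4.39 in IN@OMVs 1, while 6.482 in IN@OMVs 2 and 6.634 in IN@OMVs 3 lay within the Control range of 6.055 to 7.035. Acute phase and IL-1 or IL-17 type targets fell in 14 of 17 genes (median -3.06, adjusted p = 0.0095 with an estimated correlation), and neutrophil granule genes, which overlap the neutrophil markers, in 11 of 12 (adjusted p = 0.0507 with an estimated correlation).

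The first pattern is that neutrophil markers and acute phase genes were lower together in IN@OMVs. Fewer neutrophils in the sort, which a CD11b+ F4/80+ gate should already exclude for the most part, may account for the markers, since 12 of 12 measured were lower in all 3 IN@OMVs libraries than in all 3 Control libraries. This stays open and cannot be told apart from lower transcription, because the log2 changes ran from -7.00 to -0.81 and a base level from other cells could make them differ. For acute phase genes the mean moved with the neutrophil marker mean within Control and OMVs by a slope of -0.141 where 0.746 was needed (split-half r of the markers 0.919), and 14 of 17 members lay under the slope their own change needs. It cannot be told apart for them either, because same-number pairs moved together give 6 orderings, too few for a permutation test, 8 of 17 slopes were positive, such as Lrg1 (0.921 of 1.27 needed) against Saa3 (-0.395 of 1.90), and the median shortfall (-0.615) was within the SD over members (1.03), while a direct effect of the treatment on macrophages was not tested.

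The second pattern is the rise of interferon-gamma response genes. Lymphocytes carried along in the sort could bring such transcripts. With the T cell marker level as a covariate the list's median was 1.15 in IN@OMVs against Control (24 of 25 calls kept). In OMVs against Control it was 0.593 (12 of 13 kept). Without IN@OMVs 1, which held many T cell transcripts, the IN@OMVs median was 1.09 and 25 of 25 calls were kept. The values without IN@OMVs 1 argue against that single library as the whole source. The T cell marker level varied more between replicates than between groups, so the covariate could change the medians little. Its values therefore do not decide on carried lymphocytes. T cell markers themselves had medians of -0.03 for OMVs and 0.23 for IN@OMVs against Control (0.40 with the block), below those of the list. In their mean log2 CPM, mainly IN@OMVs 3 lay above the Control library of its number (3.103 against 1.948). Interferon made by lymphocytes in the tumour, and a direct effect of vesicles on macrophages, were not tested.

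The third pattern is that IN@OMVs 1 stood apart from the other 8 libraries. Less stromal RNA in it stays open, because 11 of 13 fibroblast markers were lowest there but their low mean was seen first, so this count does not test it. A wrong label was tested on 113 genes that separate the groups: 80.5% placed it nearer the IN@OMVs mean, short of the 90% set for that test, which leaves the question open. A second test, added because the first did not decide, found 12 of 12 neutrophil markers of IN@OMVs 1 under all 6 Control and OMVs libraries. The low level of these markers had been seen first, so this count is no independent test. Their list was fixed beforehand, however, and its mean log2 CPM was 1.61 in IN@OMVs 1 and 3.75 to 4.92 in those 6 libraries. None of the 6 thus showed the low level that an exchanged IN@OMVs library would bring. These values argue against an exchange of IN@OMVs 1 with a Control or OMVs library, while other labelling errors stay open. No biological explanation was tested, since the design gives none for 1 library.

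Each comparison of 3 libraries with 3 has 10 splits, too few for a share under 0.05. For OMVs against Control the real split called 55 genes and the highest of the others 0, for IN@OMVs against Control 858 and 0, and for IN@OMVs against OMVs 373 and 0. In each case 1 of the 10 splits, the real one, called as many. In both comparisons with Control the real split is 1 of 4 that part all 3 same-number pairs, and the other 3, which exchange the groups of 1 pair, called 0 genes. The splits that part fewer pairs called 0 as well.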
